A study of Mus musculus with 12 samples.

How the data were processed

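RNA was measured in C17.2 cells, an established mouse neural progenitor line. Per the labels' protocols, the cells grew in DMEM/F12 with serum, and neural differentiation was induced by a change to Knockout DMEM with GlutaMAX and N2 supplement, which holds no serum by the recipe given. RNA came from isolated mitochondria and from nuclei at 0, 1 and 2 h after that change. Per the labels, this gives 6 groups of 2 libraries, 12 libraries in all. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with the NEBNext Ultra II kit. Whether the libraries kept strand information is not stated, so a gene and an overlapping or antisense partner cannot be told apart in these values.

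The authors' upstream steps are known only in part. The submitters' processing notes name HISAT2, StringTie and edgeR and the genome builds GRCm38 and mm10, without versions, order or settings.

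The deposited gene table was made with SeqMonk, per the name the authors gave it, and the authors gave its values in log2 units of RPM, the reads of a gene scaled to the library's total. Each library's lowest value stood for a gene without a read, and taking it as 0.9 read turned 99.994 to 100.0 percent of the values of a library into whole reads, within 0.05 read. The recovered scaling total of a library was 30.26 M to 42.29 M reads (median 35.7 M), while 4566444 to 9256523 of its reads lay inside the listed genes. The table held 35373 entries. Of these, 52 repeated a gene and were left out, which left 35321 genes. GENCODE M21, on GRCm38, held 35250 of their identifiers, and 99.79% of the matched entries lay within 5 kb of that annotation's gene. Coordinates are those of GRCm38.

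The deposited transcript table holds FPKM values, per the file headers, from StringTie. It lists 7153 transcripts, whose numbers run to 123574, so it is part of a longer list. It was read for 11 libraries. Nuclei 1 h replicate 1 was not used here on this scale. Both pairwise sheets that the authors deposited hold FPKM of 1 library per time, mitochondria 0 h against 1 h and nuclei 0 h against 2 h, with the difference of the pair and no test, per the file headers. All 13 mitochondrially encoded mRNA genes stood at the floor of the gene table in every library, so mitochondrially encoded RNA was taken from the transcript table alone, which holds 33 such transcripts (13 mRNAs, the others rRNAs and tRNAs).

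Genes were tested with limma 3.58.1 in R 4.3.3. The design had assigned a test to each unit the table could hold, and its case for log2 values was used. The model had a mean for each of the 6 groups over the 12 libraries, with a variance trend and robust moderation. Genes above the floor in at least 2 libraries were tested (21079 genes), and the threshold was a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Contrasts were each pair of times within a fraction, mitochondria against nuclei over the 3 times, and the difference between the fractions in the 1 h effect and in the 2 h effect. The design, the gene lists, the rule for named genes and most other settings were fixed before the data were examined. Transcripts in FPKM were tested in the same way on log2(FPKM + 1) when at least 2 libraries reached an FPKM of 1.

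Most genes moved together with time on the deposited scale, by more than 0.1 in the median log2 fold change. Effects are therefore given after quantile normalization between the libraries, a setting written down in advance, with the deposited-scale counts beside them. Errors after a ± sign are standard errors of the limma model unless SD is written, and each time and fraction has n = 2 libraries. A p-value here measures only the spread between these libraries.

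The test was tried on simulated libraries, with reads drawn from negative binomial distributions around the real gene means and library totals at a dispersion of 0.01, for mitochondria 1 h against 0 h, over 21249 genes. Of 100 genes changed 2-fold, 38% were called, and 76.6% of the 47 with at least 50 mean reads. Of 97 genes changed 4-fold, 53.6% were called, and 100% of the 45 with at least 50 mean reads. Of 21052 unchanged genes 0.014% were called, and 3.2% of all calls were false. The simulation held no library split and no shared shift, and was not quantile normalized. In the real data, chi-square per degree of freedom between the 2 libraries of a group was 9.79 to 13.45 at 0 and 1 h. It was 1.93 and 2.03 at 2 h. The simulated shares therefore do not give the power or the false calls of the real tests.

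The rule for named genes took, per contrast, genes past the threshold on the deposited scale whose groups of libraries did not overlap, whose mean lay above the median of the tested genes, and whose symbol was not a predicted or clone name. The 10 largest changes in each direction were named. Where fewer than 5 passed, the places up to 5 went to the smallest p-values, named as not past the threshold. For each gene list the 4 members of smallest p served as examples, of which the text gives some. Nes, Sox2, Tubb3, Dcx, Malat1, Rmrp, Pnpt1 and Fos were to be given where needed, whatever their values. Dcx stood at the floor of the gene table in every library and was not tested.

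The gene lists covered mitochondrially encoded mRNAs, mitochondrially encoded rRNAs and tRNAs, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, mitochondrial RNA handling, the tricarboxylic acid cycle, glycolysis, nuclear-retained long non-coding RNAs, histones, small nuclear and nucleolar RNAs, non-coding RNAs linked to mitochondrial import in textbooks, and signs of ribosomal RNA precursors. They also covered immediate early and serum response genes, cholesterol biosynthesis, the ATF4 and amino acid response, p53 targets, heat shock, G2/M, endoplasmic reticulum and secreted protein mRNAs, and markers of neural progenitors, neurons, astrocytes, oligodendrocytes, microglia and blood, and fibroblasts. H1f0, a linker histone made outside S phase, was on the list of replication-dependent histones. Each list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, on the deposited scale, and again with an estimated correlation. That made 22 lists and 198 tests. Members past the threshold were counted over all genes and adjusted over the list alone.

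The share of FPKM on mitochondrially encoded transcripts was compared between fractions with a two-sided exact permutation test. Single-library checks of copies and of library sets used Fisher's exact test over genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.

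Other settings written down in advance and run were quantile normalization, no filter beyond a read in at least 1 library (23206 genes), the replicate number as a block, that number with the time as a block of 6 pairs, each library left out in turn, only the 6 libraries of a fraction, an estimated correlation for the lists, mRNAs only for the mitochondrially encoded level, direction only for the authors' sheets, and mitochondrially encoded genes left out. Chosen after seeing the data were median centring, at least 10 reads in 2 libraries, recovered reads with voom, a term for a split of the libraries into sets of 4 and 8, that term with quantile normalization, only the 8 libraries with and without quantile normalization, and a block with crossed numbers. Also chosen then were quantile normalization for the list tests and the authors' sheets, the split term and the replicate block for the list tests, left-out libraries for the list tests and the mitochondrially encoded level, and for that level another denominator and labels exchanged within a time.

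Lars2, which alone held 6.14 to 9.51% of the reads inside genes, takes the top rank in every library, and quantile normalization sets its change to 0. It was left out of the changes on that scale. Some results for single genes are not reported here.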

Results

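The series follows RNA in the first hours after C17.2 cells, a mouse neural progenitor line, are switched from serum to a neural differentiation medium. By its title, it concerns nuclear-encoded RNA and mitochondria in that switch. RNA was sequenced from isolated mitochondria and from nuclei at 0, 1 and 2 h, with n = 2 libraries for each of the 6 groups. No group at 1 or 2 h was left without the change or given fresh serum medium. Effects of differentiation, of lost serum and of the change itself can thus not be told apart. Reads inside genes numbered 6417239 and 6496357 in the mitochondrial libraries of 0 h, 5038913 and 6385769 at 1 h, and 5668226 and 5571791 at 2 h. In nuclei they numbered 7859687 and 9256523 at 0 h, 4566444 and 4575696 at 1 h, and 5503573 and 5913678 at 2 h. Each library showed a read for 17461 to 19011 genes. Mitochondria and nuclei name these preparations throughout. Mitochondrially encoded transcripts held 3.02% of the FPKM in the former and 2.63% in the latter, so no large enrichment of mitochondrial RNA was seen, and a value given for mitochondria does not place an RNA in the organelle.

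Over the time course a smaller share of each library's reads fell inside genes. Mitochondrial libraries held 20.05% ± 1.63 (SD, n = 2) of their reads in genes at 0 h, 15.9% ± 0.248 at 1 h and 15.5% ± 0.453 at 2 h. Nuclear libraries held 21.7% ± 0.311 at 0 h, 13.96% ± 0.0707 at 1 h and 14.985% ± 0.672 at 2 h. Because the deposited values are scaled to all reads, the median log2 fold change of all genes against 0 h was -0.22 at 1 h and -0.28 at 2 h in mitochondria, and -0.64 and -0.51 in nuclei. Changes named from here on are log2 fold changes after quantile normalization, with their standard error. That step removed more than a common shift, by amounts that differed between genes. At 1 h in mitochondria Arrdc3 went from 3.37 on the deposited scale to 3.56, and Malat1 from -0.53 to -0.01. Counts on the deposited scale follow in each passage, and list tests by camera are on that scale unless quantile normalization is named.

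**Figure D1:**
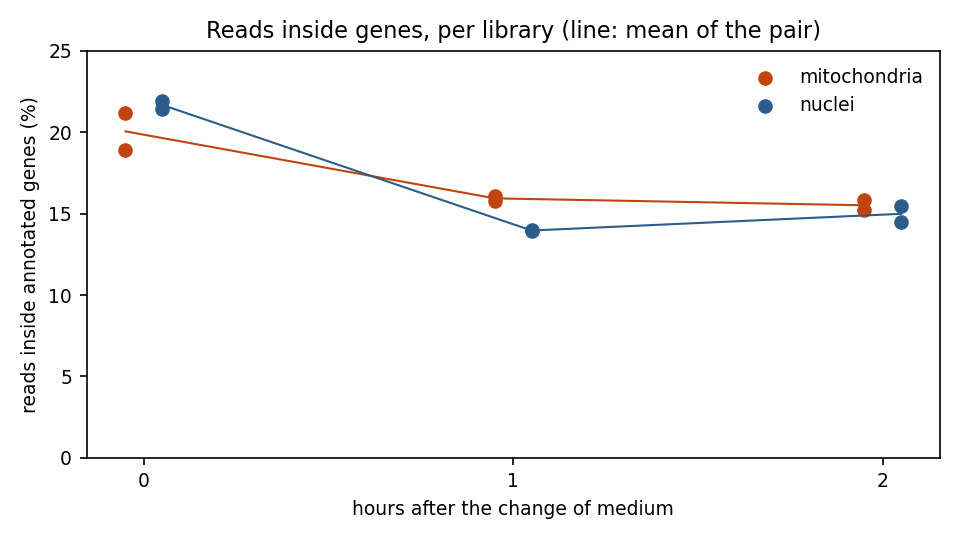
Percent of each library's reads that lie inside genes (vertical axis) against hours after the change of medium (horizontal axis). Each library has a point, and a line runs through the mean of each pair. All 4 libraries of 0 h lie between 18.9% and 21.89%, and all 8 later libraries between 13.91% and 16.11%.

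Rps27, Rpl17, Rpl23a and Gapdh had far fewer reads in 4 libraries than in the other 8. The 4 were mitochondria 0 h replicate 2, mitochondria 1 h replicate 1, nuclei 0 h replicate 1 and nuclei 1 h replicate 1. Between the mitochondrial libraries of 0 h, Rpl17 had 2078 and 13 reads, Rps27 1928 and 36, and Gapdh 5396 and 179, while the Rps27 copy Rps27rt had 14 and 896 and Wdr89 had 48 and 1061. Of 151 genes lower by over 1 log2 unit in the 4 libraries, 71 (47.0%) have a processed pseudogene named after them, against 1.8% of the other genes (Fisher's exact test over genes, two-sided p = 6.7e-76). This split took 45.4% of the variance on the first principal component over 10136 genes. It crosses the groups of 0 and 1 h, with 1 library of each group on each side, but all 4 libraries of 2 h lie on the side of the 8. Genes with such copies, most cytosolic ribosomal protein genes among them, are therefore not named for a change with time, and counts are given also with a model term for the split.

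**Figure D2:**
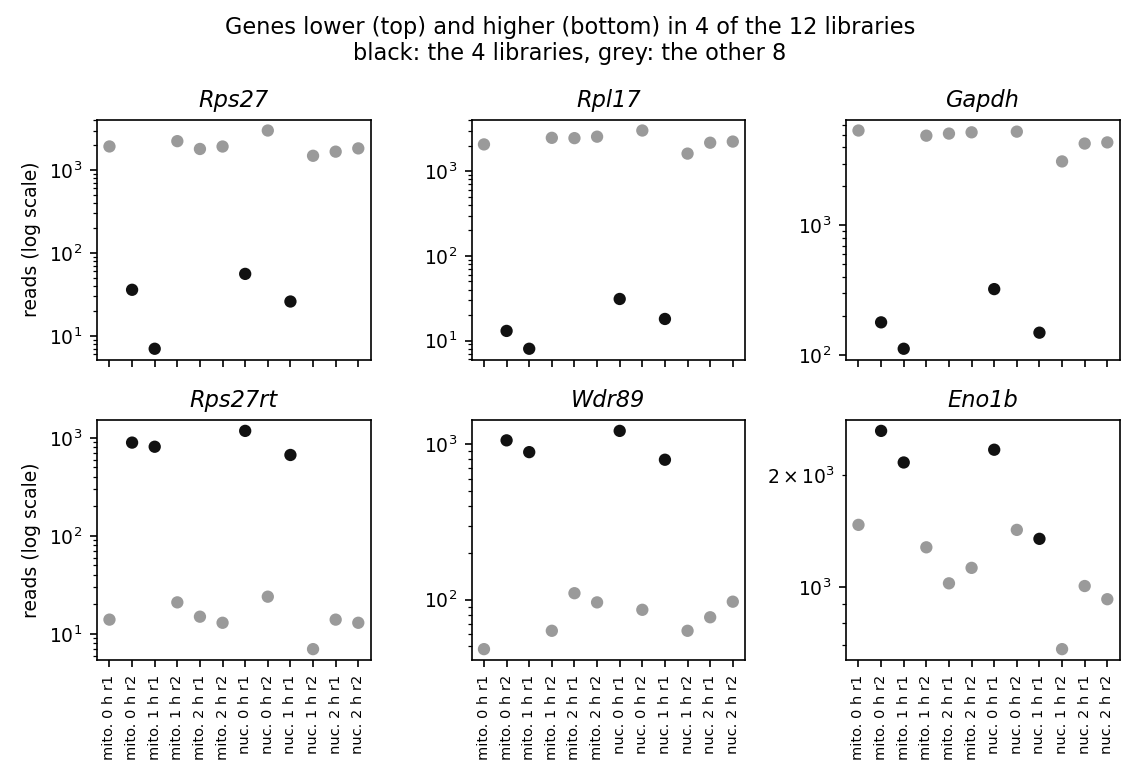
Reads per library (vertical log axis) for Rps27, Rpl17 and Gapdh in the top panels and Rps27rt, Wdr89 and Eno1b in the bottom panels, with black for the 4 libraries that stand apart and grey for the other 8. Rps27 had 7 to 56 reads in the 4 and 1488 to 3002 in the other 8.

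The first comparison asks which RNAs changed in the mitochondrial preparation within 1 h. Arrdc3, an alpha-arrestin on chromosome 13 (80883384 to 80896042, GRCm38), rose by 3.56 ± 0.13 (11.8-fold; limma, adjusted p = 4.8e-08). Its relatives Txnip, which restrains glucose uptake, and Arrdc4 rose by 2.20 ± 0.08 (chromosome 3, 96557957 to 96561883) and 1.74 ± 0.18. The transcription factor genes Egr1 (chromosome 18, 34859823 to 34864984) and Atf3 rose by 2.14 ± 0.10 and 1.80 ± 0.26, and Slc16a6 and Osgin1 by 1.76 ± 0.16 and 1.47 ± 0.16. Vwa1, Rsrp1, Adcy3, Wdr19, Prelp, Ccng2, Tmem44 and Hyal2 fell, by 1.18 (Hyal2, ± 0.21) to 1.72 (Vwa1, ± 0.36); the cyclin gene Ccng2 fell by 1.27 ± 0.24.

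Of 47 immediate early and serum response genes 20 rose in mitochondria at 1 h and 27 did not pass (27 rose, adjusted over the list alone), with Klf10 at 1.40 ± 0.09 and Ier2 at 1.38 ± 0.12. The list was higher than other genes by camera (adjusted p = 1e-16, and adjusted p = 0.02 with an estimated correlation). Of 27 endoplasmic reticulum and secreted protein mRNAs 24 fell and 3 did not pass (25 fell, adjusted over the list alone), among them the endocytic receptor Lrp1 (-0.68 ± 0.04) and the collagen Col6a1 (-0.78 ± 0.06); camera gave an adjusted p = 1.8e-26 and an adjusted p = 0.26 with an estimated correlation. Of 66 genes on the histone list 21 rose and 45 did not pass (29 rose, adjusted over the list alone), camera adjusted p = 4.6e-13 and adjusted p = 0.14 with an estimated correlation. H1f4 rose by 0.87 ± 0.06, and H1f0, a linker histone made outside S phase, by 1.06 ± 0.08. Of 25 cholesterol synthesis genes 5 fell, with Sqle at -0.51 ± 0.06, and 20 did not pass (8 fell and 1 rose, adjusted over the list alone; camera adjusted p = 2.7e-06, and adjusted p = 0.36 with an estimated correlation). Deposited values gave 16 rises and 1 fall of immediate early genes, 27 falls of endoplasmic reticulum and secreted protein mRNAs, 11 rises and 2 falls on the histone list and 13 falls of cholesterol synthesis genes.

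In all, 472 genes rose and 789 fell in mitochondria at 1 h, against 148 and 3782 on the deposited scale, 574 and 1114 with median centring, and 751 and 955 with the split term. Without replicate 1 or 2 of 0 h, or replicate 1 or 2 of 1 h, 196, 244, 234 and 359 genes rose and 533, 404, 515 and 450 fell. Only 1 gene rose past the threshold in the 8 libraries alone, where the groups of 0 and 1 h keep 1 library each and are assumed to vary like those of 2 h.

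The same question was asked of nuclei. Arrdc3 again showed the largest rise among the named genes, by 3.40 ± 0.13 (10.5-fold, adjusted p = 8.4e-08), followed by Atf3 (2.37 ± 0.26), Fosb (2.20 ± 0.29), Txnip (2.17 ± 0.08) and Egr1 (2.05 ± 0.10). The zinc exporter gene Slc30a1, the glutathione-degrading enzyme gene Chac1, Slc16a6 and Osgin1 rose by 1.85 ± 0.16, 1.82 ± 0.10, 1.75 ± 0.16 and 1.73 ± 0.16. Rsrp1 fell by 1.79 ± 0.14, Ccng2 by 1.48 ± 0.24, Dsel by 1.10 ± 0.18, Tle2 by 1.01 ± 0.19 and Clk1, a kinase of splicing factors, by 1.01 ± 0.15. Neat1, the scaffold RNA of paraspeckles (chromosome 19, 5824708 to 5845478), fell by 1.20 ± 0.08, and Malat1 of nuclear speckles by 0.51 ± 0.07.

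Of 47 immediate early genes 20 rose in nuclei at 1 h and 27 did not pass (30 rose, adjusted over the list alone), with Klf10 at 1.46 ± 0.09; on the deposited scale 10 rose and 11 fell. Camera gave an adjusted p = 2.7e-07 and an adjusted p = 0.17 with an estimated correlation. Of 66 histone-list genes 16 rose and 50 did not pass (29 rose, adjusted over the list alone), whereas 3 rose and 22 fell on the deposited scale (camera adjusted p = 0.04, and adjusted p = 0.62 with an estimated correlation). Of 14 nuclear-retained long non-coding RNAs Neat1, Malat1 and Kcnq1ot1 (-0.42 ± 0.08) fell and 11 did not pass (4 fell, adjusted over the list alone), whereas 10 fell on the deposited scale. Of 23 ATF4 and amino acid response genes 8 rose and 15 did not pass (13 rose and 1 fell, adjusted over the list alone), whereas 2 rose and 10 fell on the deposited scale. Of 27 endoplasmic reticulum and secreted protein mRNAs 2 fell and 1 rose at a list median of -0.02 (5 and 2, adjusted over the list alone), and after quantile normalization camera did not call the list (adjusted p = 0.47). All 27 fell on the deposited scale, where camera gave an adjusted p = 2.7e-07 and an adjusted p = 0.51 with an estimated correlation. In all, 214 genes rose and 171 fell, against 107 and 10120 on the deposited scale, 597 and 181 with median centring and 347 and 311 with the split term. Leaving out replicate 1 or 2 of 0 h, or replicate 1 or 2 of 1 h, gave 72, 61, 167 and 123 rises and 23, 29, 127 and 55 falls. With limma in the 8 libraries alone 0 passed, and 2515 had an unadjusted p under 0.05.

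In mitochondria at 2 h, stress response genes were among the largest named rises. Chac1 (chromosome 2, 119351229 to 119354381), the pseudokinase gene Trib3 (chromosome 2, 152337422 to 152344032) and Ddit3, which codes for the stress transcription factor CHOP (chromosome 10, 127290774 to 127296288), rose by 2.83 ± 0.10, 2.69 ± 0.14 and 2.58 ± 0.12, or 7.13-, 6.47- and 5.98-fold. Atf3 rose by 3.34 ± 0.26 (10.1-fold), Arrdc3 by 2.69 ± 0.13, Slc16a6 by 2.65 ± 0.16, Arrdc4 by 2.63 ± 0.18, Slc30a1 by 2.55 ± 0.16, Ciart by 2.35 ± 0.18 and Txnip by 2.13 ± 0.08. Rgs16, a regulator of G-protein signalling, fell by 2.20 ± 0.11. Dusp6, a phosphatase of ERK (chromosome 10, 99263231 to 99267489), Hyal2, Wdcp, Chst12, Lncpint, Neat1, Ccng2, Bmp4 and Mir100hg fell by 1.41 (Mir100hg, ± 0.11) to 1.55 (Hyal2, ± 0.21).

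Of 23 ATF4 and amino acid response genes 15 rose in mitochondria at 2 h and 8 did not pass (18 rose, adjusted over the list alone), Atf4 itself by 1.46 ± 0.06. Camera gave an adjusted p = 1.4e-17 and an adjusted p = 0.039 with an estimated correlation. Of 66 histone-list genes 37 rose and 29 did not pass (46 rose, adjusted over the list alone; camera adjusted p = 1.1e-23, and adjusted p = 0.039 with an estimated correlation), with H1f0 at 1.48 ± 0.08 and H4c14 at 1.18 ± 0.08. Of 27 endoplasmic reticulum and secreted protein mRNAs 23 fell and 4 did not pass (25 fell and 1 rose, adjusted over the list alone; camera adjusted p = 7e-18, and adjusted p = 0.38 with an estimated correlation). Of 20 G2/M genes 7 fell, with the mitotic kinase genes Plk1 (-0.72 ± 0.09) and Bub1b (-0.55 ± 0.09) among them, and 13 did not pass (8 fell and 1 rose, adjusted over the list alone; camera adjusted p = 3.7e-08, and adjusted p = 0.38 with an estimated correlation). Of 47 immediate early genes 8 rose, Klf10 by 1.79 ± 0.09 among them, and 8 fell, Ccn1 (-0.93 ± 0.08) and Egr1 (-0.63 ± 0.10) among them (10 and 10, adjusted over the list alone), whereas 7 rose and 17 fell on the deposited scale. There 12 ATF4 response genes rose and 3 fell, 22 histone-list genes rose and 2 fell, and all 27 endoplasmic reticulum and secreted protein mRNAs and 17 G2/M genes fell.

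In all, 981 genes rose and 1431 fell in mitochondria at 2 h, against 358 and 5376 on the deposited scale, 845 and 2342 with median centring, and 1108 and 1263 with the split term. Without replicate 1 or 2 of 0 h, or replicate 1 or 2 of 2 h, 537, 555, 586 and 546 rose and 889, 649, 771 and 734 fell. In the 8 libraries alone 23 rose and 10 fell.

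In nuclei at 2 h the largest named rises were those of Atf3 (3.75 ± 0.26, 13.5-fold), Chac1 (3.26 ± 0.10, 9.57-fold), Trib3 (3.12 ± 0.14, 8.68-fold) and Slc30a1 (3.12 ± 0.16). Slc16a6, Arrdc3, Ddit3, Arrdc4, Ciart and Gadd45a rose by 2.34 (Gadd45a, ± 0.13) to 2.59 (Slc16a6, ± 0.16). Ccng2 (chromosome 5, 93267257 to 93276231) fell by 3.09 ± 0.24, Rgs16 by 2.09 ± 0.11, Dusp6 by 1.66 ± 0.18, the mitotic kinesin gene Kif20b by 1.54 ± 0.09, Mir100hg by 1.51 ± 0.11, Klhl24 by 1.47 ± 0.11, Rfx3 by 1.45 ± 0.20 and Cebpd by 1.43 ± 0.24. Neat1 and Malat1 fell by 1.27 ± 0.08 and 0.40 ± 0.07.

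Of 23 ATF4 and amino acid response genes 19 rose in nuclei at 2 h and 4 did not pass (20 rose, adjusted over the list alone), Atf4 by 1.26 ± 0.06. Camera gave an adjusted p = 1.6e-19 and an adjusted p = 0.057 with an estimated correlation. Of 20 G2/M genes 9 fell, with the mitotic kinesin gene Kif11 at -0.58 ± 0.07 and Kif20a at -0.46 ± 0.08, and 11 did not pass (12 fell and 1 rose, adjusted over the list alone; camera adjusted p = 5.1e-08, and adjusted p = 0.51 with an estimated correlation). Of 66 histone-list genes 23 rose and 43 did not pass (29 rose, adjusted over the list alone), whereas 8 rose and 14 fell on the deposited scale (camera adjusted p = 0.00053, and adjusted p = 0.51 with an estimated correlation). H1f0 rose by 1.53 ± 0.08. Of 25 cholesterol synthesis genes 11 rose and 14 did not pass (16 rose, adjusted over the list alone), whereas 6 fell on the deposited scale. Among the 27 endoplasmic reticulum and secreted protein mRNAs 7 fell and 1 rose (8 and 1, adjusted over the list alone), with camera at an adjusted p = 0.0089 after quantile normalization. All 27 fell on the deposited scale, where camera gave an adjusted p = 3.3e-09 and an adjusted p = 0.51 with an estimated correlation. There 11 ATF4 response genes rose and 1 fell, and 19 G2/M genes fell. In all, 979 genes rose and 1171 fell, against 336 and 8031 on the deposited scale, 954 and 1611 with median centring and 1095 and 1103 with the split term. Leaving out replicate 1 or 2 of 0 h, or replicate 1 or 2 of 2 h, gave 409, 437, 516 and 483 rises and 340, 594, 584 and 522 falls, and in the 8 libraries alone 5 rose and 1 fell.

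**Figure D3:**
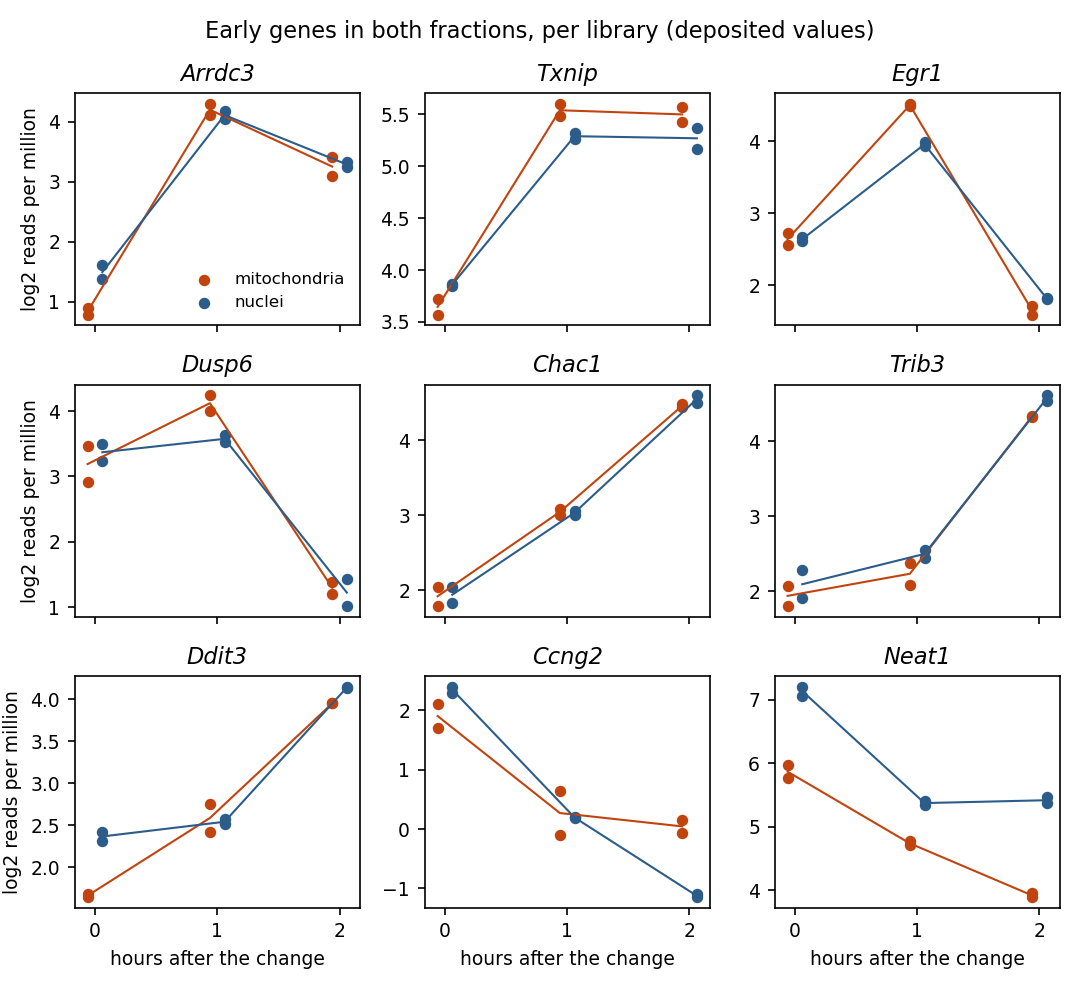
Deposited log2 reads scaled to the library's total (vertical axis) against hours (horizontal axis) for 9 genes, with a point per library and a line through the mean of each fraction. Arrdc3, Txnip and Egr1 stand highest against 0 h at 1 h, with changes of 3.37, 1.89 and 1.87 on this scale in mitochondria.

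The direct tests of 2 h against 1 h ask what changed within that hour. Egr1 fell by 2.76 ± 0.10 in mitochondria and 2.35 ± 0.10 in nuclei, and Dusp6 by 2.74 ± 0.18 and 2.58 ± 0.18, while Rgs16 fell by 1.93 ± 0.11 and 1.43 ± 0.11. The growth factor response genes Spry2 (mitochondria, -1.47 ± 0.16) and Ier3 and Ccn1 (nuclei, -1.40 ± 0.14 and -1.18 ± 0.08) fell as well. Over the same hour Trib3 rose by 2.10 ± 0.14 and 2.00 ± 0.14, Sesn2 by 1.75 ± 0.12 and 1.63 ± 0.12, Gadd45a by 1.57 ± 0.13 and 1.41 ± 0.13, Chac1 by 1.43 ± 0.10 in both, and Ddit3 by 1.37 ± 0.12 and 1.51 ± 0.12. In nuclei Rnf144a rose by 1.35 ± 0.12.

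Of 47 immediate early genes 19 fell in mitochondria between 1 and 2 h and 3 rose (24 and 6, adjusted over the list alone), and 18 fell and 1 rose in nuclei (25 and 4, adjusted over the list alone). Camera gave an adjusted p = 5.1e-12 in mitochondria (adjusted p = 0.026 with an estimated correlation) and 7.8e-15 in nuclei (adjusted p = 0.014 with an estimated correlation). Of 23 ATF4 and amino acid response genes 15 rose in each fraction and 8 did not pass (17 in mitochondria and 19 in nuclei, adjusted over the list alone; camera adjusted p = 1.1e-28 and 2.6e-28, and adjusted p = 0.021 and 0.014 with an estimated correlation). Of 25 cholesterol synthesis genes 13 rose in mitochondria and 6 in nuclei (18 and 14, adjusted over the list alone; camera adjusted p = 9e-18 and 2e-11, and adjusted p = 0.054 and 0.15 with an estimated correlation). Hmgcs1 rose by 0.77 ± 0.07 and 0.57 ± 0.07. Deposited values gave 18 falls and 2 rises of immediate early genes in mitochondria and 15 and 2 in nuclei, 15 and 18 rises of ATF4 response genes, and 10 rises of cholesterol synthesis genes in each fraction. In all, 340 genes rose and 445 fell in mitochondria (259 and 436 on the deposited scale, 387 and 1086 with median centring, 441 and 403 with the split term), and 241 rose and 266 fell in nuclei (445 and 91 on the deposited scale, 258 and 1171 with median centring, 270 and 247 with the split term). In nuclei the balance of rises and falls thus turned with the scaling.

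Single libraries carried weight in these counts between 1 and 2 h. Without replicate 1 or 2 of 1 h, or replicate 1 or 2 of 2 h, 154, 200, 211 and 179 genes rose and 129, 294, 153 and 135 fell in mitochondria. In nuclei 144, 151, 97 and 110 rose and 135, 211, 77 and 88 fell. With limma in the 8 libraries alone 0 passed in either fraction, and 2999 in mitochondria and 2926 in nuclei had an unadjusted p under 0.05.

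**Figure D4:**
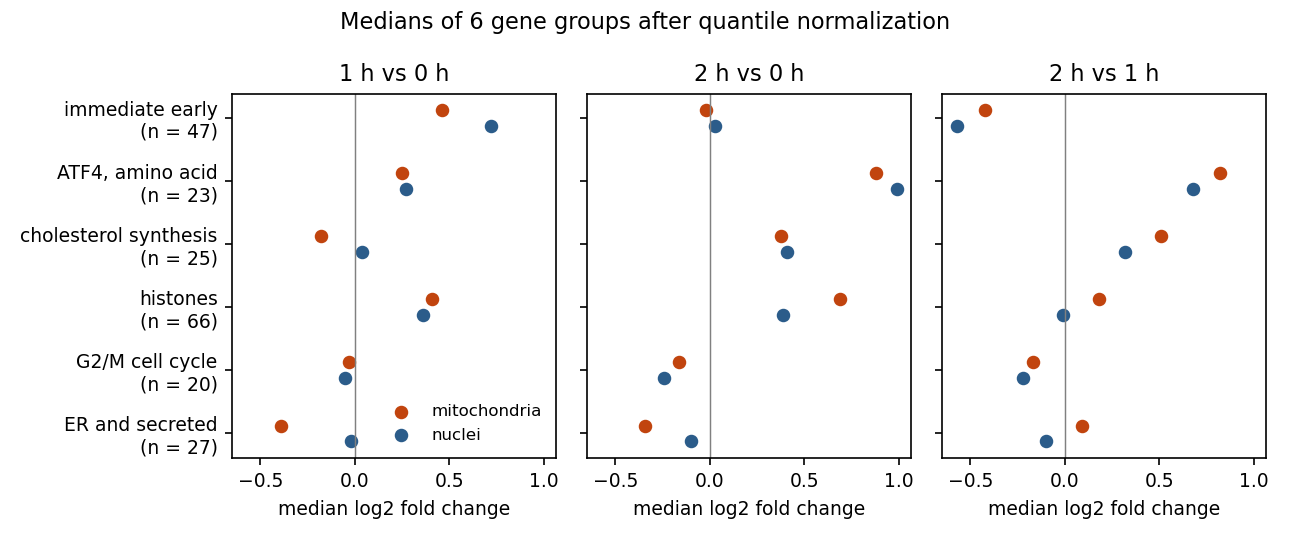
Median log2 fold change after quantile normalization (horizontal axis) of 6 gene lists in mitochondria and nuclei, for 1 h against 0 h, 2 h against 0 h and 2 h against 1 h. Immediate early genes stood at 0.46 and 0.72 at 1 h and at -0.42 and -0.57 between 1 and 2 h, while the ATF4 list stood at 0.88 and 0.99 at 2 h.

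The fractions share no library, though whether they share cultures stays open, and their changes overlapped. At 2 h 491 genes rose in both fractions, against 45.6 by chance, and 606 fell in both, against 79.5 by chance. At 1 h 94 rose in both (4.8 by chance) and 50 fell in both (6.4 by chance). Pearson's r between the fractions' changes was 0.41 at 1 h and 0.77 at 2 h across 10136 genes, which are not independent replicates (Spearman's rho 0.32 and 0.66). The library split enters the 2 h change of both fractions alike, since the set of 4 holds 1 library of 0 h from each and none of 2 h. With the split term 554 genes rose in both at 2 h (57.6 by chance) and 554 fell in both (66.1 by chance), at r = 0.70 (rho 0.62).

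The comparison of mitochondria with nuclei over the 3 times asks which RNAs each preparation held more of. The RNase P RNA gene Rpph1 (chromosome 14, 50807449 to 50807767) was lower in mitochondria by -2.69 ± 0.05 (adjusted p = 2.3e-11), and the RNase MRP RNA gene Rmrp (chromosome 4, 43492783 to 43493063) by -2.15 ± 0.05 (adjusted p = 1.6e-10). Ccnb1ip1 (-2.65 ± 0.04) and Ccdc107 (-2.12 ± 0.08) overlap these genes at 50789248 to 50807732 and 43492900 to 43495921, and their reads cannot be assigned to them with certainty. The RNase P-like Rprl3 and Rprl2, which resemble each other, stood at -2.60 ± 0.05 and -2.55 ± 0.19, and Scarna2, an RNA of Cajal bodies, at -1.72 ± 0.04. Dancr, Snhg3 and Snhg20, which lie with small nucleolar RNAs or carry them, were lower by -1.37 (Snhg20, ± 0.09) to -1.49 (Dancr, ± 0.10).

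Net1, an exchange factor of RhoA (chromosome 13, 3882018 to 3918220), was 2.78-fold higher in mitochondria (1.47 ± 0.06, adjusted p = 5.6e-08). Zbtb12, Cplx2 and the small GTPase gene Rab13 (chromosome 3, 90213695 to 90226385) were higher by 1.36 ± 0.12, 1.31 ± 0.07 and 1.31 ± 0.16. The neurofilament gene Nefm was higher by 1.09 ± 0.07, the cytochrome b5 reductase gene Cyb5r3 (chromosome 15, 83153494 to 83172592) by 1.07 ± 0.05 and Trak2, an adaptor of mitochondria to kinesin (chromosome 1, 58900449 to 58973430), by 1.07 ± 0.05. Arhgap11a, the dynein light chain gene Dynll2 and Sh3pxd2a were higher by 1.03 ± 0.05, 0.94 ± 0.04 and 0.93 ± 0.04.

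Of 14 nuclear-retained long non-coding RNAs 9 were lower in mitochondria, 1 was higher and 4 did not pass (9 and 1, adjusted over the list alone), with Neat1 at -1.27 ± 0.05, Kcnq1ot1 at -0.85 ± 0.05 and Malat1 at -0.80 ± 0.04. Camera gave an adjusted p = 1.5e-06 and an adjusted p = 0.13 with an estimated correlation. Of 7 small nuclear and nucleolar RNAs 4 were lower and 3 did not pass (5 lower, adjusted over the list alone; camera adjusted p = 6.3e-06, and adjusted p = 0.06 with an estimated correlation). All 3 tested RNAs that textbooks link to mitochondrial import, Rmrp, Rpph1 and Terc (-1.17 ± 0.18), were lower in mitochondria. Of 20 tricarboxylic acid cycle genes 6 were higher, with Pdha1 at 0.28 ± 0.04, and 14 did not pass (11 higher, adjusted over the list alone; camera adjusted p = 1.2e-10, and adjusted p = 0.18 with an estimated correlation). Of 19 glycolysis genes 4 were higher, with Hk2 at 0.27 ± 0.05, and 15 did not pass (5 higher, adjusted over the list alone; camera adjusted p = 0.00015, and adjusted p = 0.3 with an estimated correlation). Deposited values gave the same counts for the long non-coding RNAs and the 3 import-linked RNAs, 5 lower for small nuclear and nucleolar RNAs, and 10 and 6 higher for the tricarboxylic acid cycle and glycolysis.

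In all, 933 genes were higher and 1093 lower in mitochondria, against 1089 and 1755 on the deposited scale, and 1198 and 1286 with the split term. With median centring 4503 were higher and 962 lower, so the balance depends on the scaling, and with replicate number and time as a block on the deposited scale 215 were higher and 559 lower. Without a library of nuclei at 0 h, 576 or 512 were higher and 635 or 739 lower (replicates 1 and 2), and without replicate 2 of nuclei at 2 h, 593 and 765. In the 8 libraries alone 25 were higher and 22 lower.

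**Figure D5:**
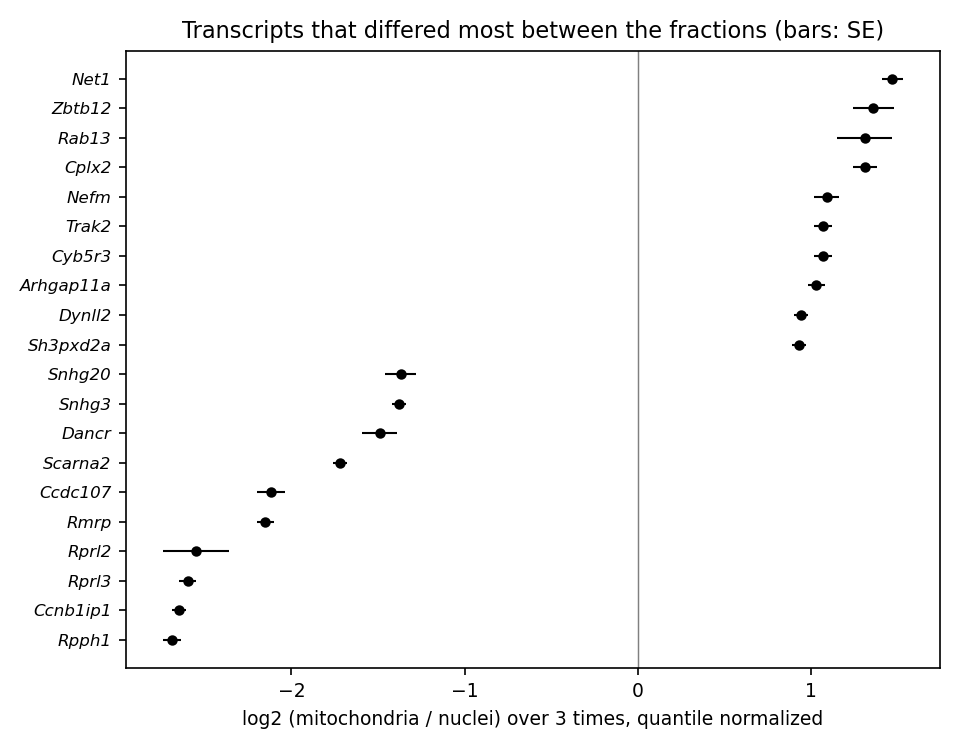
Log2 fold change between mitochondria and nuclei over the 3 times after quantile normalization (horizontal axis) of the 20 genes named by rule, with bars for the standard error. Values run from -2.69 for Rpph1 to 1.47 for Net1.

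The share of mitochondrially encoded transcripts was compared between the preparations. They held 3.02% ± 0.851 (SD, n = 6 libraries) of the FPKM in mitochondrial libraries and 2.63% ± 0.826 (SD, n = 5) in nuclear libraries, a ratio of 1.146 (exact two-sided permutation test, p = 0.498). With time the share fell from 4.07% at 0 h to 2.37% and 2.62% in mitochondria, and from 3.53% to 1.99% (n = 1) and 2.06% in nuclei. Exchanging fractions only within a time, a test chosen after seeing the data, gave a mean difference of 0.491 percentage points (exact two-sided permutation test, p = 0.0093, the smallest that 108 arrangements allow). Of the 13 mRNAs 7 were higher in mitochondria over the 3 times and 6 did not pass, with mt-Co2 at 0.25 ± 0.03 and mt-Cytb at 0.33 ± 0.05 on the FPKM scale. Of 20 rRNAs and tRNAs 6 were higher and 14 did not pass.

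On the FPKM scale the other transcripts also stood lower than at 0 h. Their medians were -0.20 at 1 h and -0.33 at 2 h in mitochondria and -0.58 (n = 1 library) and -0.49 in nuclei. The 13 mitochondrially encoded mRNAs had medians of -0.54 and -0.40 in mitochondria and -0.68 (n = 1 library) and -0.65 in nuclei. The share of other transcripts that passed was not counted, so the falls below are not set apart from the shared fall. At 1 h 8 of 13 fell in mitochondria, mt-Co3 by 1.09 ± 0.09 (limma, adjusted p = 0.0051) and mt-Atp6 by 1.08 ± 0.12 (adjusted p = 0.012). In the 1 nuclear library of 1 h the changes of the 13 ran from -1.15 to -0.46. At 2 h 6 of 13 fell in mitochondria and 13 of 13 in nuclei, mt-Nd3 there by 1.23 ± 0.09 (adjusted p = 0.0023). The complex I subunit gene mt-Nd4 rose in mitochondria, by 0.70 ± 0.12 at 1 h (adjusted p = 0.027) and 0.83 ± 0.12 at 2 h (adjusted p = 0.016), and its 2 h change differed between fractions by 1.64 ± 0.16 (adjusted p = 0.023). It was the only 1 of the 13 to rise. Its neighbour mt-Nd4l did not rise with it, at -0.50 ± 0.10 and -0.29 ± 0.10 in mitochondria. How FPKM was assigned between these 2 was not tested, so the rise may not be one of the RNA. Of 20 mitochondrially encoded rRNAs and tRNAs 16 fell in mitochondria at 1 h, and 15 in mitochondria and 17 in nuclei at 2 h. In nuclei at 1 h (n = 1 library) their median was -1.04.

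The difference between the fractions in the 1 h effect asks which RNAs responded unequally. Bc1, a small non-coding RNA of neurons (chromosome 7, 144914470 to 144914637), had a 1 h fold change 3.57-fold higher in mitochondria than in nuclei (1.84 ± 0.14, adjusted p = 0.00036). Lrp1 changed by -0.68 ± 0.06 in mitochondria relative to nuclei (adjusted p = 0.0015), and the matrix protein genes Hspg2 (perlecan) and Ecm1 by -0.65 ± 0.06 and -1.18 ± 0.14. Rpph1 moved the other way (0.94 ± 0.13), a call lost with voom on recovered reads (0.59, adjusted p = 0.52). Of 27 endoplasmic reticulum and secreted protein mRNAs 12 had a lower 1 h effect in mitochondria than in nuclei and 15 did not pass (21 and 1 the other way, adjusted over the list alone), with a list median of -0.43. Camera gave an adjusted p = 1.4e-11 and an adjusted p = 0.45 with an estimated correlation. Of 25 cholesterol synthesis genes 3 had a lower effect and 22 did not pass (8, adjusted over the list alone). Of 14 nuclear-retained long non-coding RNAs 2 passed in the other direction (5, adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation). Deposited values gave 10 endoplasmic reticulum and secreted protein mRNAs with a lower effect in mitochondria and 1 with a higher, 1 cholesterol synthesis gene with a lower and 5 long non-coding RNAs the other way.

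In all, 69 genes had a higher 1 h effect in mitochondria than in nuclei and 188 a lower, against 1573 and 82 on the deposited scale, 65 and 608 with median centring, and 223 and 392 with the split term. Without replicate 1 or 2 of mitochondria 0 h, 27 and 6 passed upward and 133 and 19 downward. When replicate 1 or 2 of mitochondria 1 h was left out, they were 12 and 41 upward and 85 and 61 downward. When replicate 1 or 2 of nuclei 0 h was left out, they were 8 and 2 upward and 60 and 3 downward, and without replicate 1 or 2 of nuclei 1 h 28 and 25 upward and 70 and 119 downward. With limma in the 8 libraries alone 0 passed, and 2354 had an unadjusted p under 0.05. On the deposited scale Ecm1 lost its call without replicate 1 of mitochondria 1 h or replicate 1 of nuclei 0 h (-0.87 and -0.76). Bc1, Lrp1 and Hspg2 kept theirs whichever of the 8 libraries was left out.

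For the 2 h effect Bc1 was the gene whose change differed between fractions (1.61 ± 0.14, adjusted p = 0.0015). On the deposited scale 3 genes passed upward and 1 downward, Bc1 among them at 1.75 on that scale, with median centring 18 and 224 passed, and with the split term 76 and 133 after quantile normalization. On the deposited scale Bc1 lost its call without replicate 1 of mitochondria 2 h or either replicate of nuclei 0 h (1.72, 1.75 and 1.76). With limma 0 passed after quantile normalization in the 8 libraries alone, and 2000 had an unadjusted p under 0.05. Of 27 endoplasmic reticulum and secreted protein mRNAs 16 had a lower effect in mitochondria at 2 h and 1 a higher when adjusted over the list alone (list median -0.28; 0 with limma over all genes on either scale, where 19 and 1 had an unadjusted p under 0.05 after quantile normalization; camera adjusted p = 1.7e-07, and adjusted p = 0.75 with an estimated correlation).

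Some markers of progenitors and neurons passed. Nes, a progenitor filament gene, fell in mitochondria by 0.28 ± 0.06 at 2 h; in nuclei it stood at 0.19 ± 0.06 at 1 h and 0.07 ± 0.06 at 2 h, without passing. There the call depended on the setting: with the split term and quantile normalization it passed as a rise (0.19, adjusted p = 0.0039, and 0.12, adjusted p = 0.024), as it did with voom and, at 1 h, with median centring, whereas on the deposited scale it passed as a fall (-0.39 and -0.41). Sox2 fell in nuclei by 0.86 ± 0.18 at 1 h (adjusted p = 0.039) and stood at -0.41 ± 0.18 at 2 h, and in mitochondria at -0.17 ± 0.18 and -0.53 ± 0.18. The neuronal tubulin gene Tubb3 rose by 0.49 ± 0.14 in mitochondria (adjusted p = 0.041) and 0.93 ± 0.14 in nuclei (adjusted p = 0.0016) at 2 h, though not on the deposited scale (0.14 and 0.35). Nefm rose in nuclei at 2 h by 1.19 ± 0.13. Pnpt1, a mitochondrial RNA-processing enzyme gene, fell in nuclei at 2 h by 0.45 ± 0.09. Of 17 neuronal markers 2 rose and 1 fell in mitochondria at 2 h and 3 rose in nuclei, of 17 progenitor markers 3 rose and 2 fell in mitochondria and 2 rose and 1 fell in nuclei, and the rest did not pass. Adjusted over the list alone, 2 neuronal markers rose and 1 fell in mitochondria and 3 rose and 1 fell in nuclei, and 7 progenitor markers rose and 4 fell in mitochondria and 2 rose and 1 fell in nuclei. Deposited values gave 1 rise and 4 falls of neuronal markers in mitochondria and 1 and 3 in nuclei, and 2 rises and 7 falls of progenitor markers in mitochondria and 14 falls in nuclei. Camera gave the neuronal list in nuclei an adjusted p = 0.023 (0.016 after quantile normalization) and an adjusted p = 0.51 with an estimated correlation.

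Markers of other cell types were also counted at 2 h. Of 8 astrocyte markers 1 rose and 1 fell (Gja1, -0.46 ± 0.09) in mitochondria and 1 rose in nuclei. Of 9 oligodendrocyte markers 2 rose and 1 fell in each fraction, Mbp rising by 2.32 ± 0.49 in mitochondria. Of 10 fibroblast markers 2 fell in mitochondria and 4 in nuclei, with camera adjusted p = 4e-04 and 0.026, adjusted p = 0.014 and 0.23 after quantile normalization, and adjusted p = 0.39 and 0.51 with an estimated correlation. None of 5 microglia and blood markers passed with limma, and 1 of them had an unadjusted p under 0.05 in mitochondria. Adjusted over the list alone, the counts of astrocyte markers were the same, 3 oligodendrocyte markers rose and 2 fell in mitochondria and 2 rose and 1 fell in nuclei, and 3 and 4 fibroblast markers fell. Deposited values gave 9 and 8 falls of fibroblast markers, 2 rises and 5 falls of oligodendrocyte markers in mitochondria and 1 and 4 in nuclei, 1 rise and 1 fall of astrocyte markers in mitochondria and 1 fall in nuclei, and 1 fall of microglia and blood markers in mitochondria.

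For lists of mitochondrial and metabolic function the counts depended on the scale, and those after quantile normalization at 2 h come first. Of 78 nuclear-encoded oxidative phosphorylation genes 2 rose in mitochondria at 2 h, and 2 rose and 4 fell in nuclei. Of 78 mitochondrial ribosomal protein genes 9 rose in mitochondria, and 3 rose and 1 fell in nuclei. Of 26 mitochondrial RNA handling genes 1 rose and 1 fell in mitochondria, the latter the mitochondrial RNA polymerase gene Polrmt (-0.68 ± 0.11), and 3 rose and 1 fell in nuclei. Of 20 tricarboxylic acid cycle genes 2 rose in nuclei, and of 19 glycolysis genes 2 rose and 2 fell in mitochondria, with Slc2a1 at -0.64 ± 0.10, and 2 rose and 1 fell in nuclei. Of 79 cytosolic ribosomal protein genes 3 rose in mitochondria and 1 in nuclei, at list medians of 1.33 and 1.12, which were 0.23 and 0.02 with the split term, where 32 rose in mitochondria and 9 rose and 6 fell in nuclei. Of 14 p53 targets 3 rose and 3 fell in mitochondria and 2 rose and 1 fell in nuclei, and of 13 heat shock genes 2 fell in each, Hsph1 by 0.39 ± 0.08 in mitochondria. Adjusted over the list alone, 9 mitochondrial ribosomal protein genes rose in mitochondria and 1 in nuclei, 2 oxidative phosphorylation genes rose and 4 fell in nuclei, and 4 RNA handling genes rose and 1 fell in nuclei. On that basis 2 tricarboxylic acid cycle genes rose and 1 fell and 2 glycolysis genes rose and 2 fell in nuclei, and 5 p53 targets rose and 3 fell in mitochondria and 3 rose and 3 fell in nuclei. Deposited values gave 25 falls of oxidative phosphorylation genes in mitochondria and 54 in nuclei at 2 h (64 in nuclei at 1 h), 9 and 47 of mitochondrial ribosomal protein genes (69 in nuclei at 1 h), 6 and 17 of RNA handling genes, 12 and 16 of tricarboxylic acid cycle genes, 6 (with 1 rise) and 8 of glycolysis genes, 3 and 5 of cytosolic ribosomal protein genes, 7 (with 2 rises) and 11 (with 1 rise) of p53 targets, and 5 and 6 of heat shock genes. In nuclei at 2 h camera placed oxidative phosphorylation and mitochondrial ribosomal proteins below other genes (adjusted p = 0.00083 and 0.0069, and adjusted p = 0.51 for both with an estimated correlation), but not after quantile normalization (adjusted p = 0.56 and 0.092). After it, mitochondrial ribosomal proteins stood above other genes in mitochondria (camera adjusted p = 3.9e-07 at 1 h and 7.2e-06 at 2 h), which they did not on the deposited scale (adjusted p = 0.19 and 0.65, and adjusted p = 0.81 and 0.91 with an estimated correlation). Lars2 was the only measured member of the ribosomal RNA precursor list, and its deposited change at 2 h was -0.14 in mitochondria and -0.53 in nuclei.

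By camera 85 of 198 list tests passed on the deposited scale and 64 after quantile normalization, 48 of them in both and in the same direction. With an estimated correlation 7 held. These were the immediate early list at 1 h in mitochondria and between 1 and 2 h in both fractions, the ATF4 list at 2 h in mitochondria and between 1 and 2 h in both fractions, and the histone list at 2 h in mitochondria. In 13 of the 85 the direction was opposite to the list's median after quantile normalization, and none of these 13 passed after it. They were tricarboxylic acid cycle genes at 1 and 2 h in both fractions, mitochondrial ribosomal proteins in nuclei at both times, cytosolic ribosomal proteins in nuclei at 1 h and between fractions, and 1 case each of glycolysis, cholesterol synthesis, p53 targets, oxidative phosphorylation and histones. In 5 of the 85 the direction was opposite to the deposited median, among them histones in nuclei at 1 and 2 h and immediate early genes there at 1 h. Median and mean differed in sign in 19 list tests after quantile normalization, such as immediate early genes in mitochondria at 2 h (-0.02 and 0.10).

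The authors' sheets compare 1 library per time in FPKM. From mitochondria 0 h replicate 1 to 1 h replicate 1, 2419 transcripts were higher and 4381 lower, and 50.02% of 6623 had the same direction in the other pair of libraries. The pair in that sheet joins a library of the 8 to a library of the 4. From nuclei 0 h replicate 2 to 2 h replicate 2, 1228 transcripts were higher and 5606 lower, and 71.25% of 6702 had the same direction in the other pair. Of 4394 transcripts of tested genes in the mitochondrial sheet 3415 (77.7%) had the direction of the limma test on the deposited scale and 2090 (47.6%) that after quantile normalization. In the nuclear sheet these were 3557 (79.9%) and 2402 (53.9%) of 4454. The libraries of the sheets are also in the limma test, so these shares are not independent. FPKM and the deposited scale both keep the shared fall, which quantile normalization removes, so the 2 scales are not alike in this comparison.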

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

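The tests of the shared fall, of the library sets and of less transcription were chosen only after the results were seen, while that of secreted and membrane protein genes outside the list was written down first.

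A test of the difference itself set apart 257 genes whose 1 h effect differed between mitochondria and nuclei after quantile normalization, and 1 gene at 2 h. These counts depend on the setting. At 2 h 209 passed with the split term and quantile normalization, 242 with median centring and 401 with voom, and at 1 h without replicate 2 of nuclei 0 h only 2 passed upward and 3 downward after quantile normalization. As effects in mitochondria minus those in nuclei, Bc1 (1.84), Clk4 (1.12) and the connexin gene Gjc3 (1.07) stood above 0. Clk4 fell in nuclei (-0.79) and did not pass in mitochondria (0.33), Gjc3 rose in mitochondria (0.59) and did not pass in nuclei (-0.48), though on the deposited scale it fell there (-1.19), and Bc1 rose in mitochondria (1.07) and fell in nuclei (-0.77). Below 0 stood the secreted or membrane protein genes Prelp (-1.18), Ecm1 (-1.18), Cd82 (-1.06), Lgals3bp (-1.02), Robo1 (-1.01), Nucb1 (-1), Clu (-0.89), Lrp1 (-0.68), Fn1 (-0.66) and Hspg2 (-0.65), of which Fn1 rose in nuclei (0.50) and did not pass in mitochondria (-0.16). On the deposited scale Fn1 fell in both fractions. Its log2 values went from 10.76 and 10.64 at 0 h to 9.71 and 9.69 at 1 h in mitochondria. In nuclei they went from 9.79 and 9.77 to 9.49 and 9.4. At 2 h the gene was Bc1 (1.61). On the deposited scale, leaving out 1 library at a time, Cd82 (-0.61 to -0.82) and Lgals3bp (-0.55 to -0.81) lost their calls whichever of the 8 libraries was left out. Prelp kept its call only without replicate 1 of mitochondria 1 h, Robo1 only without replicate 2 of nuclei 1 h, and Clu only without replicate 1 of mitochondria 0 h or of nuclei 1 h. Clk4 lost it without replicate 1 of mitochondria 1 h (1.52), Gjc3 and Ecm1 without that library (1.32 and -0.87) or replicate 1 of nuclei 0 h (1.45 and -0.76), and Nucb1 without these (-0.69 and -0.66) or replicate 2 of nuclei 0 h (-0.71). Bc1 at 2 h lost it without replicate 1 of mitochondria 2 h (1.72) or either replicate of nuclei 0 h (1.75 and 1.76).

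Among 27 endoplasmic reticulum and secreted protein mRNAs, the 1 h effect in mitochondria minus that in nuclei had a median of -0.43, and a direct test of the difference passed for 12. The median of -0.43 is the pattern itself and tests nothing further. Less transcription of these genes would lower them in nuclei as in mitochondria. In nuclei alone the list's median at 1 h was -0.02. That of the 37 genes outside the list named below was -0.084 (-0.061 to 0.064 in level-matched random lists). Of these, 26 of 37 were negative and 0 passed, against a median of -0.48 with 32 falls in mitochondria. After quantile normalization a nuclear fall of like size was not seen, and a smaller part of less transcription in the pattern stays open. On the deposited scale all 27 genes of the list fell in nuclei too. There the outside genes Psap, Stt3a and Lamb2 stood at -1.14, -0.72 and -0.86 in mitochondria and at -0.76, -0.73 and -0.96 in nuclei. The outcome thus depends on the scale, and less transcription is not excluded. A loss of membrane-bound mRNAs as a class from the mitochondrial preparation predicted a lower 1 h effect in mitochondria for other such genes too. In 37 secreted, lysosomal and membrane protein genes outside the list the median after quantile normalization was -0.371 (-0.09 to 0.126 in level-matched random lists). There 34 of 37 were negative, with Grn, Psap and Igf2r at -0.70, -0.56 and -0.55, as such a loss predicted. On the deposited scale Grn, Psap and Igf2r stood at -0.4, -0.38 and -0.38, while Stt3a and Lamb2 stood at 0.01 and 0.1. At 2 h their median was -0.287 with 35 of 37 negative and 0 past the threshold. Both differences subtract the same libraries of 0 h, so the 2 h value is not separate support. Whether less endoplasmic reticulum came down with the mitochondria or the cells changed these contacts stays open.

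Most genes fell with time on the deposited scale, at 1 h in nuclei more than in mitochondria. A selective loss of nuclear-encoded RNA from mitochondria as the only cause would need the larger fall there. The median difference in the 1 h effect was 0.328 in the other direction, and summed mitochondrially encoded mRNA fell by 0.57 in mitochondria. A larger fall in nuclei with a source of its own could hide such a loss, so a part of it is not excluded. A larger share of other reads in the later libraries follows from a smaller share in genes, so it restates the fall. Rn18s FPKM lay above every 0 h library of its fraction in 7 of 7 later libraries, but by 0.10 log2 in mitochondria and 0.38 in nuclei, and this does not tell whether such reads were added. A fall of most RNA per cell would look alike in these values, which hold no added reference RNA, so it stays open.

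The libraries fell into sets of 4 and 8 that cross the groups of 0 and 1 h. Library depth would place the 4 on one side of their partners, but they had the larger total in 1 of 4 groups and the smaller in the rest. Reads placed differently between spliced genes and their processed copies may explain the sets, with an odds ratio of 48.3 for a named processed pseudogene among the lower genes, and 18.3 without cytosolic ribosomal protein genes. Among 31 genes higher in the 4 libraries, 18 (58.1%) have a single exon, against 2.7% of the others. Genomic DNA would add reads to genes, whereas 151 genes were lower by over 1 log2 unit in the 4 libraries. Rps27, for example, had 7 to 56 reads there and 1488 to 3002 in the other 8. These values argue against genomic DNA alone as the source of the lower genes. A difference in the RNA itself would not pick out genes with copies, as the lower genes did. The Rps27 copy Rps27rt also went the other way, with 670 to 1180 reads in the 4 libraries and 7 to 24 in the other 8. These values argue against a difference in the RNA alone for the lower genes with such copies. For the other lower genes it stays open, and a difference in alignment settings stays open for all.

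In data outside the comparisons of genes, transcripts without a gene name held a median of 69.84% of the summed FPKM of a library.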

How the results depend on the processing

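For the counts of genes and the named genes, median centring, the filter of 10 reads, voom, the library split, the 8 libraries and the crossed block were chosen after seeing the data, and the other settings were written down in advance. For the list calls, the mitochondrially encoded level and the authors' sheets, the estimated correlation, mRNAs only and direction only were written down in advance, and every other setting was added after. The cause of each change was not tested unless stated. Of 184 pairs of a named gene and a comparison, 181 passed on the deposited scale. After quantile normalization 177 kept direction and side of the threshold, 2 gained a call, 3 lost it and 2 turned. With median centring 179, with voom 178, with the split term 182, with that term and quantile normalization 178, with at least 10 reads 182, without the filter 183, with the replicate block 183 and in the 6 libraries of a fraction 130 of 131 did. In the 8 libraries 126 did and 58 lost their call, and with quantile normalization 34 and 148, where fewer samples were tested. Of 1100 values with a library left out, 47 lost the call. Leaving out mitochondrially encoded genes changes nothing, since they stand at the floor. Genes with few reads limit what could be seen: in simulated data 38% of 2-fold changes were found. Those data held no library split or shared shift, so the share in the real data is not known.

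Nes in nuclei turned from -0.39 at 1 h and -0.41 at 2 h to 0.19 and 0.07 with quantile normalization, 0.34 and 0.10 with median centring, 0.19 and 0.12 with the split term and quantile normalization, 0.31 and 0.15 with voom, and 0.15 and 0.088 in the 8 libraries with quantile normalization. It passed as a rise at both times with voom and with the split term and quantile normalization, and at 1 h with median centring.

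Counts are given in the order mitochondria 1 h and 2 h against 0 h and 2 h against 1 h, nuclei in the same order, mitochondria against nuclei, and the difference in the 1 h and the 2 h effect. The deposited scale gave 3930, 5734, 695, 10227, 8367, 536, 2844, 1655 and 4 genes. Quantile normalization, which gives all libraries the same distribution of values, gave 1261, 2412, 785, 385, 2150, 507, 2026, 257 and 1. Median centring gave 1688, 3187, 1473, 778, 2565, 1429, 5465, 673 and 242. Voom gave 1780, 2939, 1120, 849, 3172, 729, 3897, 698 and 401. The split term gave 3822, 5392, 383, 10514, 8263, 288, 2807, 1666 and 8, and with quantile normalization 1706, 2371, 844, 658, 2198, 517, 2484, 615 and 209. The 8 libraries gave 806, 3540, 0, 6874, 5916, 0, 59, 0 and 0 with limma, where the zeros had 2452, 2939, 3150 and 1875 at an unadjusted p under 0.05. With quantile normalization they gave 1, 33, 0, 0, 6, 0, 47, 0 and 0, where the zeros had 2999, 2515, 2926, 2354 and 2000. At least 10 reads moved the counts by over 1.5 times for 2 h against 1 h (1229 and 955) and for the differences in effect (2840 and 257), and the 6 libraries of a fraction for 2 h against 1 h (160 and 110).

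Whether the replicate numbers mark shared cultures stays open: replicate differences correlated across genes at -0.80 between mitochondria and nuclei at 0 h and 0.75 at 1 h, where 1 library of each pair is in the set of 4, and at 0.06 at 2 h, where none is. As a block the numbers gave 1156 in mitochondria between 1 and 2 h and 2593 and 264 for the differences in effect. For the genes changed, mitochondria vs nuclei over the 3 times, a block by time gave 774, and a block with mitochondria 0 h crossed gave 10 for the difference in the 2 h effect, with counts of calls only.

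Leaving out 1 library gave 2031 to 3686, 3796 to 5288, 127 to 279, 8417 to 9304, 6486 to 7572, 126 to 321, 1693 to 2511, 50 to 2106 and 0 to 8 in the same order, where a lone library is assumed to vary like the other groups. It gave 76 to 88 list calls and a ratio of mitochondrially encoded levels of 1.04 to 1.262. The 85 list calls became 7 with an estimated correlation. Of the authors' directions, 1619 in mitochondria and 2926 in nuclei were those of genes past the threshold, against 3415 in mitochondria by direction only, and 585 and 630 after quantile normalization. Settings planned for counts and a smaller pseudocount were not run, since the table holds log2 values.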

Other observations

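The tests of cell protrusion mRNAs and of other splits of the libraries were chosen only after the results were seen.

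Beyond the genes named by rule, members of further lists differed between the preparations over the 3 times, but no list's call between them held with an estimated correlation (lowest adjusted p = 0.06). Of 25 cholesterol synthesis genes 8 were lower in mitochondria than in nuclei, with Sqle at -0.44 ± 0.04 and Insig1 at -0.43 ± 0.04 after quantile normalization, and 17 did not pass (10 lower, adjusted over the list alone; camera adjusted p = 0.15, and adjusted p = 0.0013 after quantile normalization). Of 47 immediate early genes 4 were lower, Ccn1 (-0.47 ± 0.05) among them, and of 23 ATF4 response genes 5 were lower (4 and 5, adjusted over the list alone; camera adjusted p = 0.25 and 0.3, and adjusted p = 0.31 and 0.00085 after quantile normalization). Of 20 G2/M genes 5 were higher, with Kif11 at 0.23 ± 0.04, and 15 did not pass (7 higher and 1 lower, adjusted over the list alone; camera adjusted p = 3.6e-08, and adjusted p = 0.25 with an estimated correlation). Of 66 histone-list genes 11 were higher, with H2bc15 at 0.34 ± 0.05 (15 higher and 1 lower, adjusted over the list alone; camera adjusted p = 2.4e-11, and adjusted p = 0.13 with an estimated correlation). Of 27 endoplasmic reticulum and secreted protein mRNAs 5 were higher, Lrp1 (0.69 ± 0.03) and Fn1 (0.51 ± 0.05) among them, and 5 were lower (11 and 7, adjusted over the list alone; camera adjusted p = 1.7e-11, adjusted p = 0.3 with an estimated correlation, and adjusted p = 0.47 after quantile normalization). Deposited values gave 5 lower and 1 higher for cholesterol synthesis, 5 lower for immediate early genes, 4 lower and 2 higher for the ATF4 list, 9 and 23 higher for G2/M and the histone list, and 15 higher and 1 lower for the endoplasmic reticulum list.

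Some neuronal and oligodendrocyte markers were among the RNAs higher in mitochondria. Of 17 neuronal markers 5 were higher, with Tubb3 at 0.58 ± 0.08 and Map2, whose mRNA is known from dendrites, at 0.38 ± 0.07, and 12 did not pass (6 higher, adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.37 with an estimated correlation). Of 9 oligodendrocyte markers 3 were higher, with Sox10 at 0.44 ± 0.04 and Cnp at 0.41 ± 0.05, and 6 did not pass (camera adjusted p = 0.0023, and adjusted p = 0.13 with an estimated correlation). Of 13 heat shock genes 2 were higher, Hsp90ab1 (0.40 ± 0.08) among them (camera adjusted p = 0.0012, and adjusted p = 0.3 with an estimated correlation). Deposited values gave 4 neuronal, 3 oligodendrocyte and 3 heat shock genes higher.

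A hypothesis arose from Net1, Rab13, Trak2 and Dynll2, mRNAs known from cell protrusions, among the genes highest in mitochondria. If mRNAs of cell protrusions came with this preparation as a class, other members would be higher too. Of 4 members that the rule had not named, Pkp4 (0.77), Palld (0.38) and Ddr2 (0.24) were higher and Kank2 (0.07) did not pass. Their median was 0.31, against -0.164 to 0.162 in the middle 95 percent of 10000 random lists of like level. This is consistent with the hypothesis, but 4 genes chosen after the pattern was seen are few, and a source in the preparation or in the cell was not told apart.

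The difference between mitochondria and nuclei was set against other splits of the same libraries. In a model of 6 against 6 libraries without times, 1621 genes passed for the real split. It was the only 1 of 100 drawn splits to give as many, and the highest of the others gave 116. Times and the library sets also differ between the libraries, so these are not exchangeable. Every other split mixes the fractions and so leaves part of their difference in its spread. A share of 1 in 100 is also the lowest that these draws allow. The real split thus called more genes than any other drawn, but this comparison cannot decide on chance.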
